A study of Homo sapiens with 4 samples.

How the data were processed

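RNA sequencing was analysed from 4 libraries of A375 cells, 1 for each combination of 2 siRNAs (siNC and siSIRT7) and 2 radiation states (non-irradiated and irradiated). Each sample was put in its group by its labels, and each column of the gene table was matched to a sample by its name, with 0 columns of per-sample values left unmatched. Total RNA was extracted with TRIzol and sequenced with Illumina libraries, per the labels' protocols. Whether the libraries kept the strand, and how ribosomal RNA was treated, is not given in the sources used here.

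The authors deposited a table of 44591 genes that holds whole-number read counts per gene without normalization. The submitters' processing notes name HISAT2, TopHat2, Bowtie2 and HISAT and the genome build hg19, without saying which program made the alignments used. The counting program, the annotation and the versions are not given in the sources used here. The deposited table also gives RPKM, which the authors scaled by gene length and by the total count of the library. This was checked on the values: for every gene with a count, the RPKM equalled the count divided by length and total within a relative tolerance of 1e-06. The table lists gene type, length and position, of which 19233 genes are protein coding, and 12 gene names had been turned into calendar dates. Coordinates are those of the table, on hg19. With no strand stated for counting, reads of overlapping and antisense genes cannot be assigned with certainty, and reads of near-identical copies can be split between them.

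Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled with TMM factors of 1.09, 0.952, 0.986 and 0.979 (siNC and siSIRT7 non-irradiated, then siNC and siSIRT7 irradiated). Log2 ratios were taken between log2 CPM values with a prior count of 2. With 1 library per group, genes were counted by size: at least 2-fold different, with at least 50 counts in the higher library, or with at least 200 counts in the highest library for the difference between irradiation ratios. Intervals for single ratios are 95% binomial (Clopper-Pearson) intervals of the split of counts between a pair of libraries. They cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Totals of 14804902 to 19173825 counts per library make counting error small for most genes with at least 50 counts: simulated libraries that differed by counting error alone gave at most 2 genes past the size rule in any comparison. Libraries simulated with the spread fitted by the additive model gave up to 42 higher and 40 lower genes in a single comparison, more than counting error alone gave. That spread comes from departures from additivity, so it can hold real differences between states as well as noise. The 4 libraries differed from each other by more than counting noise (mean chi-square per gene of 12.7 to 32.3 in pairs), so none is the same library sequenced again.

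Average effects were tested with an additive model of siRNA and irradiation over all 4 libraries, by edgeR's quasi-likelihood test with robust dispersion after its standard filter on low counts, with Benjamini-Hochberg adjustment at 0.05. The model tested 18404 genes with 1 residual degree of freedom and a common biological coefficient of variation of 0.112. The prior degrees of freedom were estimated as infinite, so genes of like abundance share 1 value of the spread. Differences in an effect between states count as error in that shared value. A gene's own difference between states hardly enters its p-value. The standard error (SE) given with a fold change is its absolute log2 value divided by the square root of the test's F value. It therefore carries the shared spread and not the gene's own. The words rose and fell are used for genes that passed this test. The steps were tested on simulated data made for the siRNA contrast from the means and library sizes of the real genes, with 200 genes changed. In 18224 genes tested, 92% of those changed 2-fold and 47% of those changed 1.5-fold were called. Of 145 calls 6 were false, and 0 genes were called for irradiation, which had no simulated effect. The simulated spread was the one fitted by the same model, without interaction of the factors and without trends on gene length or GC content. These rates therefore check the steps and do not give the share of false calls in the real libraries.

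For 31 gene lists, the median log2 ratio of the members with a mean of at least 10 counts was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these libraries and is not a p-value. Lists with fewer than 5 such members have values without a percentile. Members past the additive test are given over all genes and adjusted over the list alone. Lists overlap in part, so a gene can be counted in more than 1 of them.

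The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names SIRT7 and the other sirtuins, then for each contrast the 10 genes highest and the 10 lowest in both states by the smaller of the 2 log2 ratios, leaving out placeholder names. It adds the 5 highest and 5 lowest differences between irradiation ratios and, for each list described, up to 4 members with the largest average log2 ratio and those past the size rule in both states. Some genes that this rule selects are not reported here. Alternatives tried were median-of-ratios and total-count scaling, a prior count of 0.5, no abundance minimum or one of 200 counts, a 1.5-fold rule, and RPKM on a log2(value + 1) scale. For the additive model they were DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters and non-robust dispersion, and for the lists a mean of at least 100 counts. Alternatives chosen after seeing the data were the removal of each library's smooth trend on log2 gene length and GC content (mgcv 1.9.3), protein-coding genes alone, and fits of 1 factor at a time. GC content was taken from GENCODE transcripts of GRCh38 matched by gene name, for 97.3% of the genes with a mean of at least 50 counts, and no coordinates of that build were used. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

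Leaving out a library was not possible in the additive model, since 3 libraries leave no residual degree of freedom, so the comparisons that do not use the siNC non-irradiated library are given beside those that do. The interaction of siRNA and irradiation was described by size and not tested, for the same reason. Protein, chromatin and reads were not analysed here.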

Results

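Gene expression was measured by RNA sequencing in A375 cells, an established human melanoma line with an activated BRAF kinase. Cells were transfected with a control siRNA (siNC) or with an siRNA against SIRT7 (siSIRT7), and each was profiled without and after irradiation. SIRT7 encodes a nuclear NAD-dependent deacylase known for roles in ribosomal RNA transcription and DNA repair. The design asks which transcripts differ with the siRNA, which differ with irradiation, and whether the difference after irradiation depends on the siRNA. The kind, dose and timing of the radiation are not given in the sources used here. Each of the 4 groups held 1 library, so a difference between a pair of libraries has no replicate check and no p-value. Total counts assigned to genes were 14804902 in the siNC non-irradiated library, 17527721 in the siSIRT7 non-irradiated library, 19173825 in the siNC irradiated library and 16934732 in the siSIRT7 irradiated library. Between 26927 and 27708 genes had at least 1 count, and between 13563 and 13940 genes had at least 50.

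The siNC non-irradiated library held more of some nuclear and intronic transcripts than the other 3. MALAT1, a nuclear-retained long non-coding RNA, took 0.542% of its counts against 0.274% to 0.329% in the other libraries, and long non-coding RNA genes as a class took 4.27% against 3.41% to 3.46%. Genes annotated as sense-intronic were higher in it than in the mean of the other libraries by a median log2 of 0.54 over 125 genes, above every one of 10000 random lists matched on expression. They were lower in the siSIRT7 non-irradiated library (-0.28) and in the siNC irradiated library (-0.14). In the siSIRT7 irradiated library they were near matched random lists (-0.07, percentile 41.2). The 1064 antisense genes were at 0.12 in the siNC non-irradiated library, at percentile 1.69. By the mean chi-square per gene that library differed most from siSIRT7 non-irradiated (32.3), followed by the pair of siSIRT7 non-irradiated and siNC irradiated (27.2), so it was not the only one to lie far from another. Trends on gene length and GC content were not confined to this library. Across 13712 genes, the Spearman correlation of a library's deviation from the other 3 with gene length was 0.27 in siNC and -0.23 in siSIRT7 without irradiation, and -0.20 and 0.067 after it. The correlation with GC content was -0.28 and -0.18 without irradiation, and 0.40 and 0.24 after it. The siNC non-irradiated library enters the siRNA comparison without irradiation and the irradiation comparison in siNC. The siRNA comparison after irradiation and the irradiation comparison in siSIRT7 do not use it.

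SIRT7 mRNA itself, at chromosome 17, positions 79869815 to 79876058 on the minus strand of hg19, was present in every library. It had 431 counts (16.8 RPKM) in siNC and 421 counts (13.9 RPKM) in siSIRT7 without irradiation, and 584 counts (17.6 RPKM) in siNC and 378 counts (12.9 RPKM) in siSIRT7 after irradiation. Its log2 ratio of siSIRT7 to siNC was -0.08 without irradiation, with a 95% counting interval of -0.28 to 0.11 under TMM scaling. After irradiation the log2 ratio was -0.44 (interval -0.63 to -0.25). In the additive fit over the 4 libraries its average log2 fold change was -0.27 ± 0.15 (SE), lower in both pairs of libraries, and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.40). Both total-count scaling and the removal of each library's trend on gene length and GC content put the value without irradiation at -0.28. The labels are used as given, which is an assumption, since the mRNA level by itself separates the libraries labelled siSIRT7 from those labelled siNC weakly. SIRT2, a mainly cytoplasmic deacetylase, was higher in siSIRT7 in both states (log2 of 0.41 and 0.32), and SIRT1, SIRT3, SIRT4, SIRT5 and SIRT6 had log2 ratios between -0.71 and 0.30. For SIRT1, SIRT3 and SIRT6 the value without irradiation (0.02, 0.02 and 0.14) turned negative under total-count scaling. None of the 7 sirtuins passed the test for either factor, over all genes or adjusted over the list alone.

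**Figure D1:**
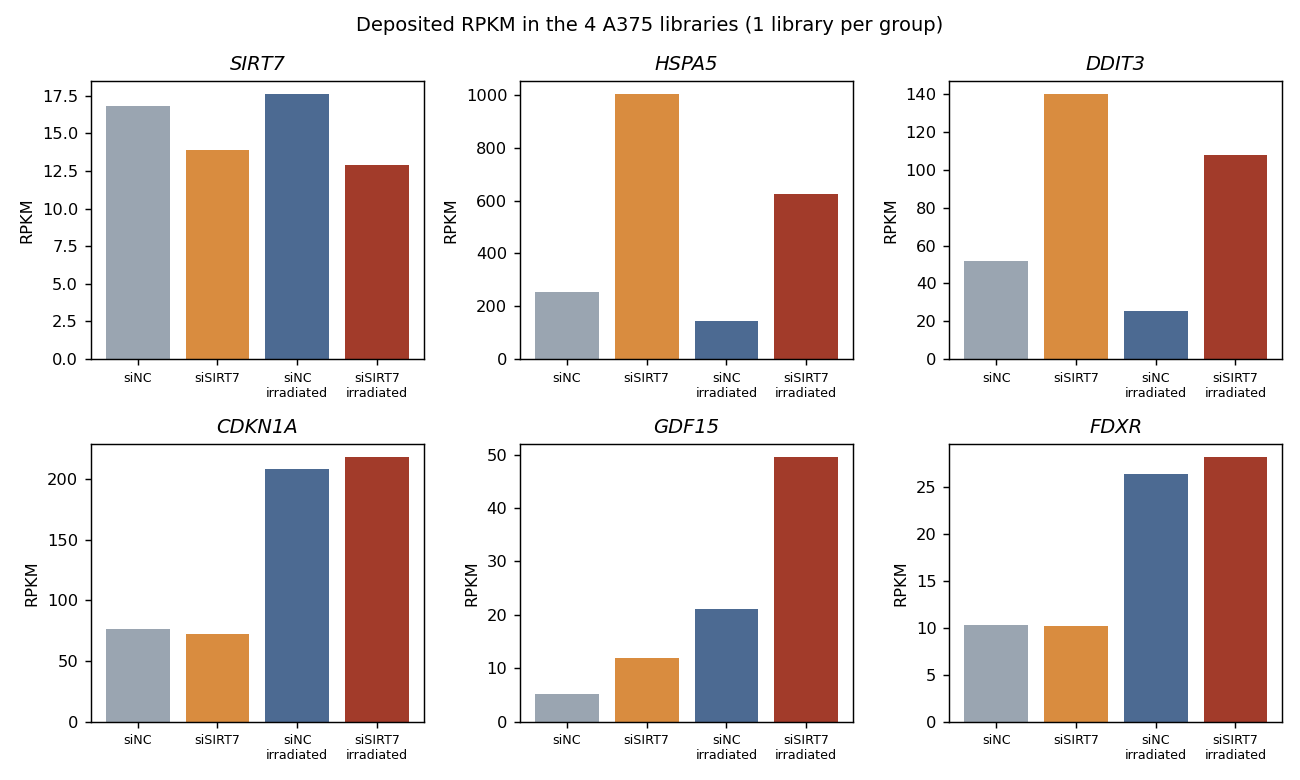
Bars show the deposited RPKM (vertical axes, each starting at 0) of 6 genes in each of the 4 libraries, 1 library per bar, with no error bar because no group has a replicate. HSPA5 stands at 254 and 143 RPKM in the siNC libraries and at 1002 and 626 RPKM in the siSIRT7 libraries, while CDKN1A stands at 76.4 and 72.6 RPKM without irradiation and at 208 and 218 RPKM after it.

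The siSIRT7 libraries had higher levels of the genes that serve protein folding in the endoplasmic reticulum. HSPA5, the major chaperone of that compartment (chromosome 9, 127997127 to 128003666, minus strand), rose 4.52-fold without irradiation and 4.41-fold after it, from 14902 to 69743 counts and from 10896 to 42101 counts. SDF2L1, MANF and PDIA4, which encode a chaperone cofactor, a secreted stress-induced factor and a disulfide isomerase, rose with log2 ratios of 1.82, 1.86 and 2.03 without irradiation and 1.73, 1.64 and 1.55 after it. HERPUD1, part of the machinery that degrades misfolded proteins, rose with log2 ratios of 1.42 and 2.51, and DDIT3, the transcription factor CHOP of the stress response, with 1.63 and 2.09. The co-chaperones DNAJC3 and DNAJB9, the transcription factor XBP1 and the chaperone HSP90B1 rose with log2 ratios between 1.07 and 1.51. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the average log2 fold change was 2.15 ± 0.28 (SE) for HSPA5 (adjusted p = 7.49e-12), 1.85 ± 0.15 for DDIT3 (adjusted p = 2.66e-29), 1.95 ± 0.17 for HERPUD1 (adjusted p = 1.18e-27) and 1.77 ± 0.15 for SDF2L1 (adjusted p = 7e-28), each higher in both pairs of libraries. The SE values carry the spread shared by genes of like abundance, and HERPUD1's own log2 ratios of 1.42 and 2.51 lie further apart than its SE. DDIT3 overlaps MARS in the annotation, so part of its counts is uncertain.

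Of the 22 genes listed for the endoplasmic reticulum unfolded protein response, 19 rose, 0 fell and 3 did not pass, and 21 rose when adjusted over the list alone. The list's median log2 ratio was 1.40 without irradiation and 0.995 after it, both above every one of 10000 random lists matched on expression. Of the 28 tested genes of ATF4 and the integrated stress response, which covers amino acid supply and the shared arm of several stresses, 15 rose, 0 fell and 13 did not pass, with 21 rising when adjusted over the list alone. Their medians were 0.68 and 0.42, again above every matched random list. Within this group TRIB3, a pseudokinase, rose with log2 ratios of 1.51 and 0.76, ADM2, a secreted peptide, with 1.14 and 1.38, and CTH, an enzyme of cysteine synthesis, with 0.86 and 1.26. DESeq2's Wald test on the same design passed 17 of the unfolded protein response genes and 7 of the ATF4 genes, and CTH was not among them.

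Genes of secreted inflammatory signalling and of growth-factor output were also higher with siSIRT7. Of 26 tested genes of the NF-kB and secreted inflammatory list, 7 rose, 0 fell and 19 did not pass (8 rose adjusted over the list alone). Among them were the cytokine LIF (log2 of 0.99 and 0.88 in the states without and after irradiation), the neutrophil chemokine CXCL8 (1.22 and 0.62), the adaptor TRAF1 (1.08 and 0.64) and the receptor-associated kinase IRAK2 (1.02 and 0.75). Of 22 immediate early genes 4 rose and 0 fell (7 rose adjusted over the list alone), namely FOSB, EGR1, EGR2 and IER3, with FOSB at 0.90 and 1.42 and EGR1 at 0.71 and 0.93. EGR2 and IER3 did not pass with DESeq2. Of 20 genes of MAPK output 3 rose and 0 fell (7 rose adjusted over the list alone). These were EGR1 and IER3, already counted as immediate early genes, and DUSP5, a nuclear phosphatase that acts on ERK, at 1.19 and 0.78. The list medians were 0.47 and 0.15 for NF-kB, 0.32 and 0.32 for immediate early genes, and 0.40 and 0.12 for MAPK output, and the percentiles among matched random lists ranged from 97.8 to 100. The medians without irradiation come from the comparison that uses the siNC non-irradiated library. For RNA polymerase I and ribosome biogenesis, the process in which SIRT7 is best known, 2 of 30 genes rose and 0 fell (4 rose adjusted over the list alone), with medians of 0.33 and 0.12 at percentiles 99.8 and 99.5. These were NOLC1, a nucleolar phosphoprotein, at 1.13 and 0.70, and POLR1E, a subunit of RNA polymerase I, at 0.75 and 0.35, which did not pass with DESeq2.

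Mitotic genes were lower with siSIRT7. The median log2 ratio of 30 G2/M and mitotic genes was -0.24 without irradiation and -0.27 after it, below every matched random list in both states. The tests called 2 of them lower and 0 higher, with 28 not passing, while 11 fell when adjusted over the list alone. ANLN, an actin-binding protein of the cleavage furrow, fell with log2 ratios of -0.48 and -0.89, and ASPM, a spindle-pole protein, with -0.77 and -0.28. Neither passed with DESeq2, and 14 of the 30 fell once the trend on gene length and GC content was removed. Of 31 genes of DNA double-strand break repair 2 fell and 0 rose (2 fell adjusted over the list alone). These were H2AFX, the histone variant marked at breaks (-0.41 and -0.50), and FANCD2, a Fanconi anaemia protein (-0.80 and -0.42), and neither passed with DESeq2. The list's median was -0.21 without irradiation, at percentile 0.05, and -0.09 after it, at percentile 7.3.

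Outside these groups, MCF2L, a guanine nucleotide exchange factor, rose with log2 ratios of 1.49 and 1.49. Among the lowest genes in both states, MELTF-AS1, a long non-coding RNA beside MELTF, fell from 229 to 90 counts without irradiation and from 172 to 57 counts after it (log2 of -1.38 and -1.37). Without strand information its reads cannot be told apart from those of MELTF. SLC34A3, a phosphate transporter, fell with log2 ratios of -1.38 and -1.27, UCN, the peptide urocortin, with -1.22 and -1.17, and the kinase ICK with -1.23 and -1.07. SGCA, NCALD, UCA1, SRSF11P1 and PLSCR4 also fell, with log2 ratios between -0.89 and -1.44, and none of these 5 passed with DESeq2. ADIRF had log2 ratios of -1.17 and -1.16 on at most 51 counts and did not pass (adjusted p = 0.06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in both pairs).

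Over all genes, 135 were at least 2-fold higher and 241 at least 2-fold lower in siSIRT7 without irradiation, of 14081 with at least 50 counts in the higher library. After irradiation these numbers were 54 and 42 of 14094. Libraries simulated with no siRNA effect and the fitted spread gave 42 and 33 genes in the first comparison and 41 and 40 in the second, so size in a single pair does not by itself mark a difference. In both states 26 genes were higher and 10 lower, against 0.42 and 0.41 from independent lists, and 11 of the 26 belong to the unfolded protein response list. These comparisons share no library. The log2 ratios of the 2 states correlated across 13712 genes with a Pearson r of 0.39 and a Spearman correlation of 0.34, where genes are not independent replicates. The additive fit tested 18404 genes with 1 residual degree of freedom and called 305 higher and 266 lower in siSIRT7 (edgeR quasi-likelihood test, Benjamini-Hochberg at 0.05). DESeq2 called 98, of which 95 were among those 571. The p-values rest on a spread shared by genes of like abundance, taken from departures from additivity in these 4 libraries. They measure neither variation between replicates nor a gene's own disagreement between states. The labels name no separate cultures. Total-count scaling shifted the log2 ratios of the comparison without irradiation by -0.19. In both states RPKM gave 30 higher and 36 lower, and no abundance minimum 191 and 309. Total-count scaling gave 77 higher and 421 lower genes without irradiation, 18 higher and 12 lower in both states, and 127 higher and 272 lower in the additive fit. Removing the trend on gene length and GC content gave 91 higher and 313 lower genes without irradiation, and RPKM gave 187 and 644. A minimum of 200 counts turned this split into 76 higher and 43 lower, the 1.5-fold rule into 1012 and 896, and protein-coding genes alone gave 98 and 103, so which direction holds more genes depends on the settings. After irradiation the split of 54 and 42 became 31 and 3 with 200 counts and 302 and 391 with the 1.5-fold rule. In the additive fit a mean of at least 50 counts gave 259 higher and 284 lower, and DESeq2 gave 88 and 10.

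**Figure D2:**
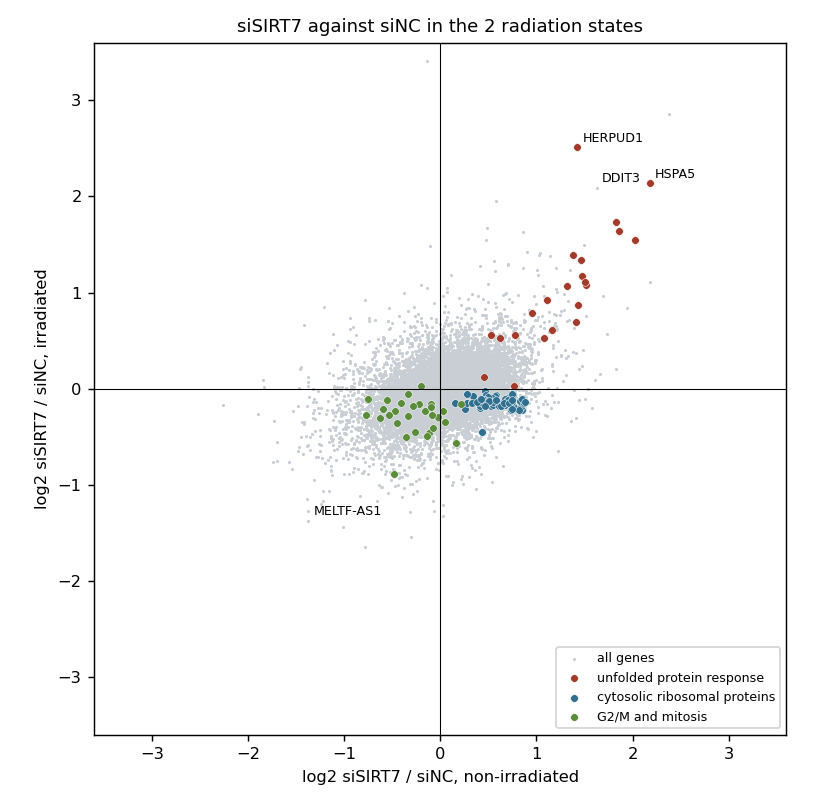
Each point is 1 of 13712 genes with a mean of at least 50 counts, placed by its log2 ratio of siSIRT7 to siNC without irradiation (horizontal axis) and after irradiation (vertical axis), with 3 gene lists in colour. The unfolded protein response genes (medians of 1.40 and 0.995) lie at the upper right, the mitotic genes (medians of -0.24 and -0.27) at the lower left, and the ribosomal protein genes (medians of 0.58 and -0.14) to the right of 0 on the horizontal axis and below 0 on the vertical axis.

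Targets of the transcription factor p53 were higher after irradiation with either siRNA. CDKN1A, the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36644237 to 36655116, plus strand), rose with log2 ratios of 1.59 in siNC and 1.55 in siSIRT7, from 2984 to 10511 and from 3357 to 9735 counts. GDF15, a secreted stress cytokine, rose 4.39-fold in siNC and 4.04-fold in siSIRT7, from 109 to 568 and from 291 to 1174 counts. FDXR, a mitochondrial reductase, rose with log2 ratios of 1.49 and 1.42, BTG2, an antiproliferative factor, with 1.42 and 1.24, and DDB2, a nucleotide excision repair protein, with 1.06 and 1.35. The average log2 fold change was 1.56 ± 0.19 (SE) for CDKN1A (adjusted p = 3.52e-13), 2.08 ± 0.16 for GDF15 (adjusted p = 1.91e-33) and 1.46 ± 0.15 for FDXR (adjusted p = 1.3e-18), each higher in both pairs of libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 29 tested p53 target genes, 20 rose, 0 fell and 9 did not pass, and 27 rose when adjusted over the list alone. Their median log2 ratio was 0.73 in siNC and 0.70 in siSIRT7, above every matched random list in both. DESeq2 passed 10 of them.

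The siRNA contrast split this list. GDF15 rose with siSIRT7 (log2 of 1.35 without irradiation and 1.23 after it), as did SESN2, a stress-induced regulator of growth signalling (0.67 and 0.43). SESN2 is also among the ATF4 and integrated stress response genes that rose. MDM2, the ubiquitin ligase that limits p53, fell with siSIRT7 (-0.79 and -0.27), as did TP53INP1, an autophagy and apoptosis factor (-1.12 and -0.39). The other 25 of the 29 did not pass. Adjusted over the list alone, 2 members rose and 3 fell, and DESeq2 passed GDF15 but not SESN2, MDM2 or TP53INP1. With the trend on gene length and GC content removed 2 rose and 4 fell. The list's median was -0.04 without irradiation, at percentile 1.47, and -0.03 after it, at percentile 20.9.

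Several genes of immune recognition, cell death and signalling rose beside them. TNFSF9 and CD70, ligands that costimulate T cells, rose with log2 ratios of 1.05 and 1.04 in siNC and 0.99 and 0.84 in siSIRT7, the members that passed of 14 tested immune checkpoint and NKG2D ligands (2 rose adjusted over the list alone). Of 15 regulators of the BCL2 family 2 rose and 0 fell (2 rose adjusted over the list alone), namely BAX (1.04 ± 0.15 SE on average) and BBC3 (0.82 ± 0.15), which promote apoptosis and are p53 targets as well. BBC3 did not pass with DESeq2. NECTIN4, an adhesion protein, rose from 17 to 87 counts in siNC and from 22 to 118 in siSIRT7. ACTA2, a smooth muscle actin and the member that rose of 22 TGF-beta target genes, had log2 ratios of 1.44 and 1.24, and overlaps FAS, so its counts are uncertain. PTCHD4, a patched-related membrane protein, rose with an average log2 fold change of 1.63 ± 0.18 (SE). INPP5D, DAPK1 and NALT1 had log2 ratios of 1.44 to 2.56 on 33 counts or fewer without irradiation, and did not pass with DESeq2.

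Genes of DNA replication were lower after irradiation. The median log2 ratio of 30 replication and S phase genes was -0.22 in siNC, at percentile 0.01 of matched random lists, and -0.47 in siSIRT7, below every one of them. Of these 3 fell, 0 rose and 27 did not pass, while 13 fell when adjusted over the list alone. RRM2, the regulated subunit of ribonucleotide reductase, fell with log2 ratios of -0.59 and -0.77, CDC6, an origin licensing factor, with -0.59 and -0.93, and MCM10, a replication initiation factor with 32 to 103 counts, with -0.71 and -1.41. Of 31 double-strand break repair genes 2 fell and 0 rose (6 fell adjusted over the list alone), among them the nuclease EXO1 (-0.75 and -0.78). Their median was -0.13 in siNC and -0.14 in siSIRT7. ZGRF1, a helicase, and the kinase SGK3 fell with log2 ratios between -0.73 and -1.01. RRM2, CDC6, MCM10, EXO1, ZGRF1 and SGK3 did not pass with DESeq2, and removing the trend on gene length and GC content ended the calls of MCM10, EXO1, ZGRF1 and SGK3. The same removal took the replication genes that fell from 3 to 6, with list medians of -0.30 and -0.46. CENPK, ZNF367 and UBE2Q2P2 had log2 ratios between -0.79 and -1.40 and did not pass.

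Mitotic genes did not share this direction. The median of the 30 G2/M genes was 0.02 in siNC, which turned negative under total-count scaling, and 0.06 in siSIRT7, at percentile 97.9. Removing the trend on gene length and GC content gave 0.08 and 0.13 (percentiles 92.2 and 99.97), with 3 genes rising. CDC20, an activator of the anaphase-promoting complex, rose (0.75 and 0.35) and was the member that passed, while 3 rose when adjusted over the list alone, and it did not pass with DESeq2.

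Unfolded protein response genes were lower after irradiation with either siRNA. HERPUD1 fell with log2 ratios of -1.24 in siNC and -0.15 in siSIRT7, SDF2L1 with -0.56 and -0.65, CRELD2 with -0.44 and -0.74, and MANF with -0.46 and -0.67. These were the members that fell of 22, with 0 rising and 18 not passing, and 10 fell when adjusted over the list alone. None of the 4 passed with DESeq2, which passed HSPA5 in their place (log2 of -0.68 and -0.72). The list's median was -0.15 in siNC and -0.49 in siSIRT7, below every matched random list in both. DDIT3 (-0.88 and -0.41) and SLC7A11 (-0.86 and -0.70), a cystine transporter, fell among the 28 ATF4 genes, where 1 rose and 3 fell when adjusted over the list alone, and neither passed with DESeq2.

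Over all genes, 79 were at least 2-fold higher and 105 at least 2-fold lower after irradiation in siNC, of 14203, and 58 were higher and 19 lower in siSIRT7, of 13838. Libraries simulated with no irradiation effect and the fitted spread gave 36 higher and 31 lower in siNC, and 32 higher and 29 lower in siSIRT7. In both siRNA states 19 genes were higher and 0 lower, against 0.21 and 0.051 from independent lists, and 6 of the 19 are in the p53 list. The log2 ratios with each siRNA correlated across 13712 genes with a Pearson r of 0.12 and a Spearman correlation of 0.079. The additive fit called 85 genes higher and 34 lower after irradiation (edgeR quasi-likelihood test, Benjamini-Hochberg at 0.05), and DESeq2 called 24, of which 21 were among those 119. Total-count scaling shifted the log2 ratios in siNC by -0.14, giving 47 higher and 158 lower genes there. A minimum of 200 counts turned the split in siNC to 26 higher and 12 lower, protein-coding genes alone to 44 and 34, the 1.5-fold rule to 531 and 541, and RPKM to 144 and 486. In siSIRT7 the split of 58 and 19 became 189 and 166 with RPKM and 244 and 227 with the 1.5-fold rule. Removing the trend on gene length and GC content gave 50 higher and 123 lower in siNC and 60 higher and 10 lower in siSIRT7.

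**Figure D3:**
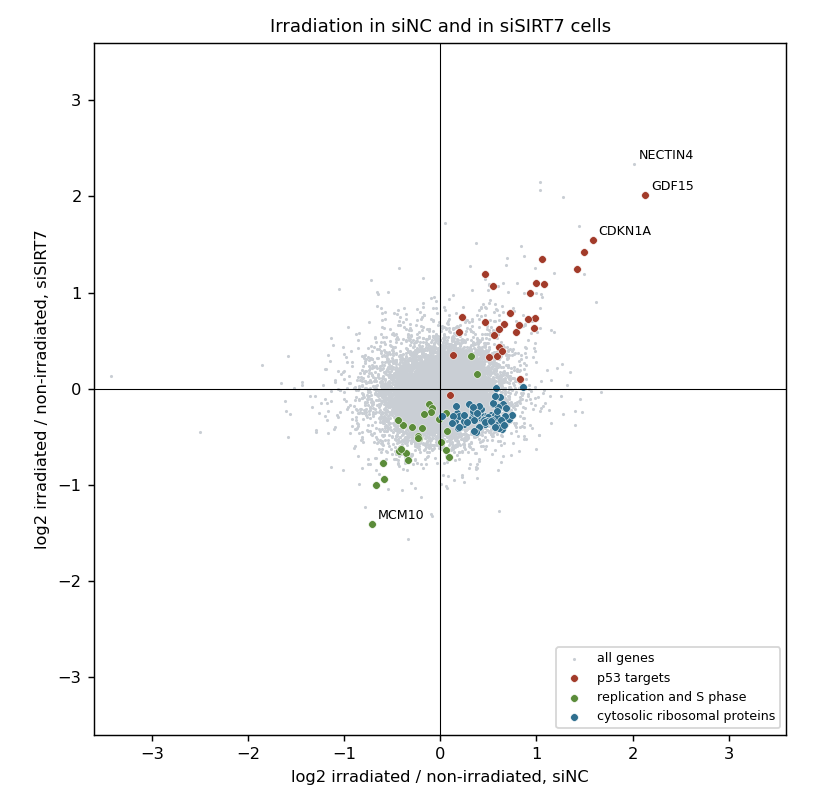
Each point is 1 of 13712 genes with a mean of at least 50 counts, placed by its log2 ratio of irradiated to non-irradiated in siNC (horizontal axis) and in siSIRT7 (vertical axis), with 3 gene lists in colour. The p53 targets (medians of 0.73 and 0.70) lie at the upper right, the replication genes (medians of -0.22 and -0.47) at the lower left, and the ribosomal protein genes (medians of 0.45 and -0.28) at the lower right.

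Genes of translation and respiration had irradiation ratios of opposite sign with the 2 siRNAs. The 71 cytosolic ribosomal protein genes had a median log2 ratio for irradiation of 0.45 in siNC, where 71 were above 0, and of -0.28 in siSIRT7, where 69 were below 0. The difference between the irradiation log2 ratios, siSIRT7 minus siNC, had a median of -0.73, against -0.32 to -0.14 in the central 95% of matched random lists. The medians of this difference were -0.46 for 30 mitochondrial ribosome genes and -0.51 for 30 oxidative phosphorylation genes. In the siRNA contrast the ribosomal protein genes had medians of 0.58 without irradiation and -0.14 after it, the mitochondrial ribosome genes 0.39 and -0.05, and the oxidative phosphorylation genes 0.32 and -0.14. Median signs in these 3 lists were the same under total-count scaling, with irradiation medians of 0.31 and -0.24, 0.12 and -0.13, and 0.20 and -0.15. None of the 71, 30 and 30 genes passed the additive test for either factor, over all genes or adjusted over the list alone. The values above 0 are those of the comparisons that use the siNC non-irradiated library, in which the ribosomal protein genes were lower than in the mean of the other libraries by a median log2 of -0.46. They were higher in the siSIRT7 non-irradiated library than in the other 3 by 0.34, and the medians of -0.14 and -0.28, which do not use the siNC non-irradiated library, lay below every matched random list. Removing the trend on gene length and GC content took the median of 0.58 to 0.32, the irradiation medians of 0.45 and -0.28 to 0.26 and -0.17, and the median of -0.73 to -0.41. It took the differences for the mitochondrial ribosome and oxidative phosphorylation genes to -0.24 each. The oxidative phosphorylation median without irradiation became 0.14, inside the central 95% of matched random lists (percentile 79.7), and the mitochondrial ribosome median 0.23 (percentile 99.9). After this removal 1 of the 30 oxidative phosphorylation genes rose in the additive test for the siRNA. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, so single values are uncertain.

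Replication genes also differed in their irradiation ratios, with a median difference of -0.27 (siSIRT7 minus siNC) at percentile 0.3, which became -0.13 at percentile 1.41 once the trend on gene length and GC content was removed. Total-count scaling brought the list's irradiation medians closer together, at -0.37 in siNC and -0.43 in siSIRT7. In the siRNA contrast this list had a median of -0.02 without irradiation and of -0.23 after it, below every matched random list in the latter. Of its 30 members 0 passed, over all genes or adjusted over the list alone, and 1 fell with the length and GC trend removed. Among single genes with at least 200 counts in the highest library, 23 had an irradiation ratio at least 2-fold higher in siSIRT7 than in siNC and 46 at least 2-fold lower, of 10718. Simulation with the fitted spread and no effect gave 13 and 15. That spread was fitted from departures from additivity, which are these same differences, so the simulated numbers are no separate reference for them. The lowest differences included COX5B, a subunit of cytochrome c oxidase (0.87 in siNC and -0.40 in siSIRT7), PDCL3, a phosducin-like chaperone cofactor (0.39 and -0.93), ZMAT5, a component of the minor spliceosome (1.03 and -0.23), and the overlapping or copied genes SLC25A5-AS1 (1.03 and -0.48) and RPL7AP6 (1.04 and -0.20). The highest were MIR663A (-2.50 and -0.45), POTEM (-1.17 and 0.35), GOLGA8B (-0.86 and 0.51), SPATA31C2 (-0.98 and 0.33) and HSD3BP4 (-0.92 and 0.28), which belong to multicopy families or overlap other genes and are uncertain. The interaction has no residual degree of freedom with 4 libraries, so none of these differences was tested. Total-count scaling turned the split of 23 and 46 into 54 and 13, removing the trend on gene length and GC content into 28 and 6, and RPKM into 205 and 70.

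**Figure D4:**
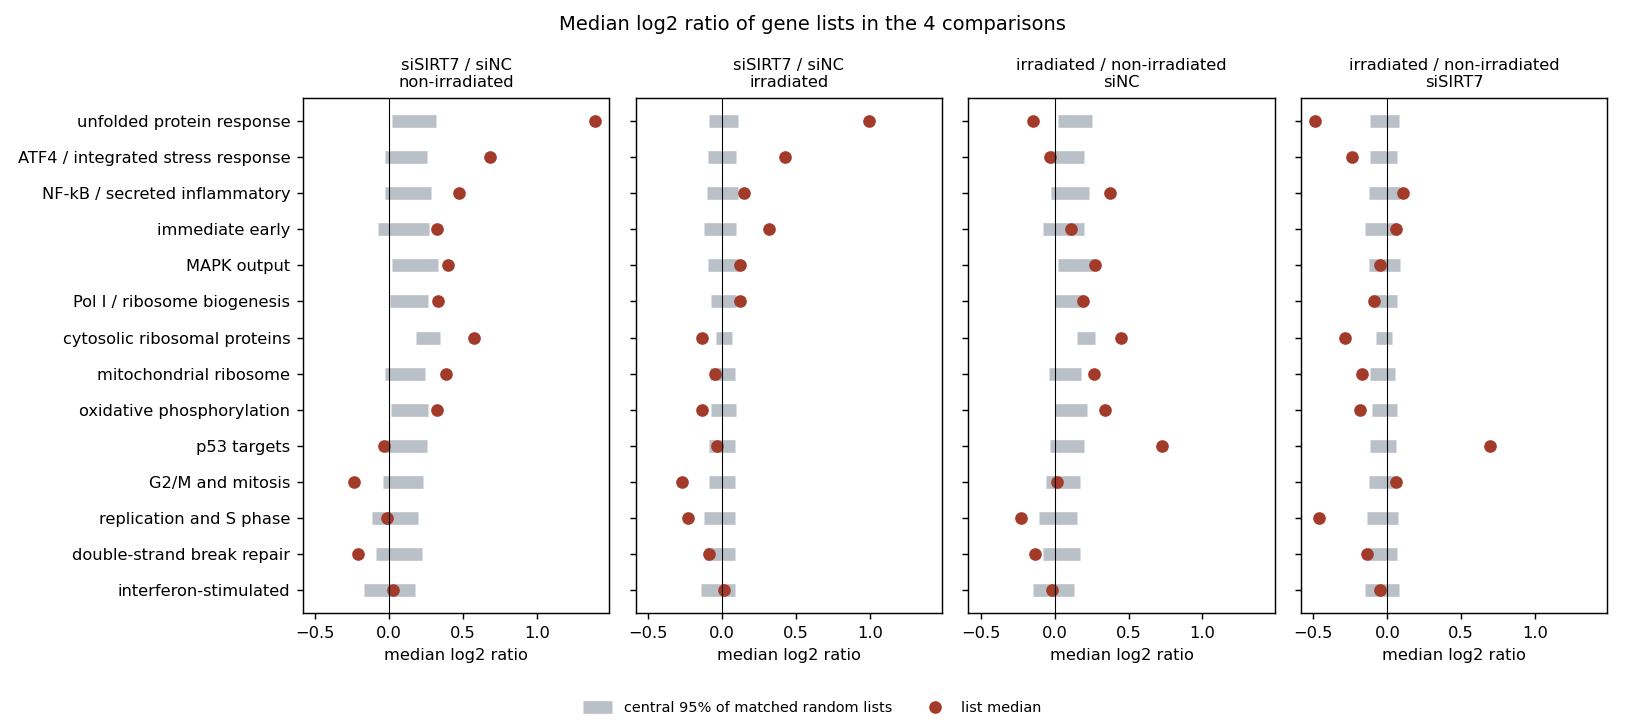
Dots show the median log2 ratio (horizontal axes) of 14 gene lists in the 4 comparisons, 1 panel each, and grey bars show the central 95% of 10000 random lists of the same size matched on expression. The unfolded protein response lies to the right of its bar in both siRNA panels (1.40 and 0.995), the p53 targets in both irradiation panels (0.73 and 0.70), and the cytosolic ribosomal proteins lie to the right in siNC (0.45) and to the left in siSIRT7 (-0.28).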

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

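The tests on gene length and GC content were written down before their results were seen, although the correction they rest on was added after the data had been examined, and the tests on sense-intronic genes, on single comparisons and on the level of SIRT7 were chosen after the result was seen.

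Genes of the cytosolic ribosome pointed in opposite directions in the paired comparisons, a difference that was not tested: their median log2 ratio of siSIRT7 to siNC was 0.58 without irradiation and -0.14 after it, and their ratio for irradiation was 0.45 in siNC and -0.28 in siSIRT7 (0.26 and -0.17 with length and GC trends removed). For the medians above 0, an effect of siSIRT7 seen only without irradiation cannot be told apart from a difference of the siNC non-irradiated library. The irradiation ratio of 0.45 in siNC is part of the pattern itself, and no group has a replicate. The medians of -0.14 and -0.28 do not use that library, and both lay below every matched random list. Within the limit of 1 library per group, they argue against a difference of that library as the whole cause. The median of -0.14 likewise argues against an siSIRT7 effect confined to non-irradiated cells as the whole cause. Bias from gene length and GC content is argued against as the whole cause, because the median of 0.58 stayed at 0.32 (percentile 99.99) once these trends were removed, although matched random lists themselves had a median of 0.26 before and 0.21 after this. More unspliced or nuclear RNA in the siNC non-irradiated library stays open as a candidate explanation of the medians above 0. Sense-intronic genes were higher there by a median log2 of 0.54, against 0.22 for matched random lists. They were lower in the siSIRT7 non-irradiated (-0.28) and siNC irradiated (-0.14) libraries, where ribosomal protein genes were higher (0.34 and 0.14). In the siSIRT7 irradiated library both were below 0, at -0.07 (percentile 41.2) for sense-intronic and -0.04 (percentile 0) for ribosomal protein genes. Each value is set against the mean of the other libraries, so 1 high library lowers the rest by construction. The signs in the other libraries therefore add no separate evidence for this explanation. Whether the libraries differ in the cells or in their preparation was not tested.

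Of 22 genes of the unfolded protein response 19 rose with siSIRT7, and the higher level of the list did not depend on the siNC non-irradiated library: the median was 0.995 after irradiation, where that library is not used. Length and GC bias is argued against as well, with a smaller corrected median of 0.976. What stays open is whether lower SIRT7 or another effect of the oligonucleotide or its transfection accompanies the rise. These cannot be told apart with 1 siRNA condition and with SIRT7 mRNA at a log2 ratio of -0.0837 in the state where it differed less. The list's median was 1.40 in that state and 0.995 after irradiation, where SIRT7 had a log2 ratio of -0.44. With 1 library per group, other differences between the siSIRT7 and siNC libraries cannot be excluded either. As a hypothesis, loss of SIRT7 may raise these genes, which a second oligonucleotide or a rescue would test.

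Of 29 p53 targets 20 rose after irradiation in the additive test, and the list's median was above 0 with either siRNA. Both technical explanations tested are argued against: the smaller corrected median after removal of length and GC trends was 0.65, and the median in siSIRT7, which does not use the siNC non-irradiated library, was 0.70. An effect of irradiation may account for the pattern, as a hypothesis that rests on 1 library per group.

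Mitochondrial ribosome genes had a median irradiation ratio of 0.26 in siNC and of -0.17 in siSIRT7, and this difference was not tested. Once length and GC trends were removed these were 0.17 and -0.07, the latter inside the central 95% of matched random lists (percentile 3.92). Oxidative phosphorylation genes had medians of 0.32 without irradiation and -0.14 after it for siSIRT7 against siNC, and of 0.34 in siNC and -0.19 in siSIRT7 for irradiation, also without a test of the difference. With the same removal these became 0.14 and -0.07, and 0.15 and -0.06, with the first and the last inside the random range (percentiles 79.7 and 6.96). A single gene without a symbol, ENSG00000238035.4, passed the 2-fold rule for irradiation in opposite directions, with a log2 ratio of -1.05 in siNC and 1.03 in siSIRT7 on 29 to 78 counts, and this difference was not tested either.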

How the results depend on the processing

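With 1 library per group, no comparison here has replicates. The siNC non-irradiated library, which held more of some intronic and nuclear transcripts, enters the siRNA comparison without irradiation, the irradiation comparison in siNC and the additive model. The counts of genes past the size rule, and their split into higher and lower, depend on the settings, and every alternative set out beforehand was run. Among log2 values of named genes and lists that were at least 0.5 in size, 0 changed sign. For total-count and median-of-ratios scaling this was fixed in advance, since they shifted log2 ratios by at most 0.19 and 0.019. RPKM was tried on list medians and not on named genes, so this count says little about stability. Smaller values did change sign, 16 of 62 with RPKM and 7 of 62 with a list mean of at least 100 counts. Total-count scaling changed the sign of 60 of 1004, and removing the length and GC trend that of 95 of 1476. The other settings changed 0 to 6 signs. Most list medians reported here are under 0.5 in size. Values follow the order siRNA without irradiation, siRNA after irradiation, irradiation in siNC, irradiation in siSIRT7 and difference between irradiation ratios, then genes past the rule in both states and Pearson r, each for siRNA and irradiation. The main values are 376, 96, 184, 77 and 69 genes, 36 and 19 in both states, and r of 0.386 and 0.12. Without an abundance minimum they were 5022, 3016, 3998, 3875 and 6600, with 500 and 526 in both states (171 higher and 355 lower for irradiation) and r of 0.106 and 0.0383, since genes with few counts pass 2-fold easily. With a minimum of 200 counts the first 4 were 119, 34, 38 and 19, irradiation in both states gave 9, and r was 0.437 and 0.163. With RPKM, which uses total counts and another minimum, they were 831, 367, 630, 355 and 275, with 66 and 53 in both states and r of 0.236 and 0.052, and irradiation gave 16 genes higher and 37 lower in both states instead of 19 and 0. With the 1.5-fold rule they were 1908, 693, 1072, 471 and 888, with 236 and 92 in both states, a lower threshold that admits more genes by construction. With the trend on gene length and GC content removed, the difference between irradiation ratios gave 34 genes, r was 0.44 and 0.0881, SIRT7 without irradiation had a log2 ratio of -0.28 instead of -0.08, and the additive siRNA calls went from 571 to 1288; the cause was not tested. With protein-coding genes alone, siRNA without irradiation gave 201, irradiation 78 in siNC and 51 in siSIRT7, the difference between irradiation ratios 43, and r 0.409 and 0.15, with 350 and 53 additive calls against 571 and 119, since fewer genes enter. For the additive model DESeq2 called 98 genes for the siRNA and 24 for irradiation against 571 and 119, of which 95 and 21 were shared. Total-count scaling gave 58 irradiation calls and a minimum mean of 50 counts gave 74, against 119; the cause was not tested. Fits of 1 factor at a time called 251 genes for the siRNA, 3 for irradiation and 0 for the crossed split of the libraries. Each single-factor fit leaves the other factor in its error, and the crossed split leaves both there, which lowers the calls. These numbers are therefore no control for the additive fit.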

Other observations

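SLFN11 and PTGS2 are given here because of their values, chosen after these were seen, and no tests of explanations were made for any value in this part.

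Further gene lists also held genes that rose with siSIRT7, in part the same genes as in the groups described so far. SLC7A11 and DDIT4 are also among the ATF4 genes that rose, and SOD2 is among the NF-kB genes that rose. Of 23 tested genes of NRF2 and oxidative stress 3 rose and 0 fell (4 rose and 1 fell adjusted over the list alone), namely HMOX1, which degrades haem (log2 of 1.94 without irradiation and 0.84 after it), SLC7A11 (0.74 and 0.90) and the mitochondrial superoxide dismutase SOD2 (0.60 and 0.66). Of 19 heat shock genes 3 rose and 0 fell (4 rose adjusted over the list alone): the near-identical HSPA1A and HSPA1B, whose reads cannot be divided with certainty, at 0.95 and 0.26 and at 0.86 and 0.25, and AHSA1, an activator of HSP90, at 0.79 and 0.18. None of these heat shock genes passed with DESeq2. Of 24 antigen presentation genes 2 rose and 0 fell (3 rose and 2 fell adjusted over the list alone, and 3 rose and 3 fell with the length and GC trend removed). The members that rose were the peptide-loading chaperones CALR (1.41 and 0.69) and PDIA3 (1.08 and 0.52), which are also in the unfolded protein response list. The antigen presentation median was 0.20 without irradiation and -0.12 after it, where 19 of 24 genes were below 0 (percentile 0.48). Medians in the same order were 0.39 and 0.02 for NRF2, 0.36 and 0.09 for heat shock, and 0.25 and -0.06 for hypoxia and glycolysis. Of 30 hypoxia and glycolysis genes NDRG1 and DDIT4 rose (4 rose adjusted over the list alone), and of 26 genes of the undifferentiated and invasive melanoma state FN1, the matrix protein fibronectin, rose at 0.62 and 0.79 (5 rose adjusted over the list alone). Of 24 cholesterol synthesis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), and the latter was MSMO1 at -0.31 and -0.99. GPNMB, a melanosomal glycoprotein, fell at -0.27 and -0.72, the member that passed of 19 melanocyte genes (1 fell adjusted over the list alone). NDRG1, DDIT4, MSMO1 and GPNMB did not pass with DESeq2. SLFN11, a restriction factor that sensitises cells to DNA damage, rose with siSIRT7 from 254 to 543 counts without irradiation and from 168 to 395 counts after it, and PTGS2, the inducible cyclooxygenase, rose from 256 to 618 and from 365 to 643 counts.

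Other programmes had few or no calls in the siRNA contrast. Of 30 interferon-stimulated genes 0 passed for the siRNA and 0 for irradiation, over all genes or adjusted over the list alone, and the medians were 0.03 and 0.01 for the siRNA (the former turned negative under total-count scaling) and -0.02 and -0.05 for irradiation. None of 26 autophagy and lysosome genes passed for either factor, while 2 rose with siSIRT7 adjusted over the list alone and 1 passed with DESeq2, with medians of 0.28 (percentile 98.1) and 0.01. Histone H1 gene HIST1H1E rose with siSIRT7 on 23 to 57 counts, 1 of 17 replication-dependent histone genes (1 adjusted over the list alone), and lost its call with DESeq2, with limma-voom and after removal of the length and GC trend. In the same contrast 0 of 14 immune checkpoint and NKG2D ligands, 0 of 15 BCL2 family members and 0 of 22 TGF-beta targets passed, over all genes or adjusted over the list alone, while of the TGF-beta targets DESeq2 passed 1, and 1 rose and 1 fell with the length and GC trend removed. Medians were 0.23 and -0.10 for the ligands, -0.02 and 0.04 for the TGF-beta targets, and 0.16 (negative under total-count scaling) and 0.03 for the BCL2 family, whose median of average ratios was 0.18 (percentile 97.7). For irradiation, 0 genes passed of the 26 NF-kB genes, the 20 MAPK output genes, the 30 RNA polymerase I genes, the 24 antigen presentation genes, the 30 hypoxia genes, the 19 heat shock genes, the 24 cholesterol genes, the 19 melanocyte genes, the 26 invasive-state genes and the 17 histone genes, over all genes or adjusted over the list alone. DESeq2 likewise passed 0 genes of these lists, and 1 NF-kB gene rose with the length and GC trend removed. Over the whole table, 1327 of 18404 tested genes had an unadjusted p under 0.05 for irradiation in edgeR's quasi-likelihood test. With no effect a share of about 0.05 would be expected. The NF-kB list had medians of 0.38 in siNC and 0.10 in siSIRT7 for irradiation, at percentiles 100 and 98.98. ABCC2, an efflux transporter of the NRF2 list, rose after irradiation (0.40 and 0.73) and did not pass with DESeq2, and BTG2 was the member that rose of 22 immediate early genes (1 adjusted over the list alone).

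Markers of other cell types gave few calls. For the siRNA CD68 rose of 6 leukocyte markers (0.87 and 0.31; 1 adjusted over the list alone) and COL6A3 of 7 fibroblast markers (0.81 and 0.98; 1 rose and 2 fell adjusted over the list alone), and neither passed with DESeq2. Of 10 keratinocyte and epithelial markers and 4 endothelial markers 0 passed, and for irradiation 0 passed in any of these 4 lists, over all genes or adjusted over the list alone. The leukocyte markers had medians of 0.23 and 0.16 for the siRNA and 0.50 in siNC (percentile 99.3) and -0.002 in siSIRT7 for irradiation, the fibroblast markers -0.47 and 0.11 for the siRNA and -0.18 and 0.14 for irradiation, and the endothelial markers 0.10 (negative under total-count scaling) and -0.11 for the siRNA. The epithelial markers had -0.09 and -0.01 for the siRNA and 0.23 and 0.15 for irradiation, where the median of their average ratios was 0.25 (percentile 99.7).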
